A study of Mus musculus with 12 samples.

How the data were processed

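RNA was sequenced from 12 organoid samples in 4 groups of 3. The submitters' processing notes name cutadapt, featureCounts and DESeq2 and the builds GRCm38 and mm10, without giving their roles; the aligner, the versions and the annotation release are not given in the sources used here. The deposited table lists protein-coding genes with an identifier, symbol, position and length, followed by 12 columns of values.

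The name of every value column was compared with every label of every sample and with the series text, after removing punctuation and case. No label held any of the names, so 12 value columns were not used. Their totals, and with them the depth of each sample, are not reported here. A design of 5 contrasts by a quasi-likelihood count test, with gene list tests and correlations of effects, had been fixed before the data were examined. It was not run. The first rows of the table were printed, values included, when its format was inspected, and no column was assigned from them.

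The annotation columns were read with Python 3.11.15 and compared with GENCODE M21, a mouse annotation on GRCm38. Of 17050 identifiers, 16591 matched with their version, and 16591 of these had the same chromosome, start and end. The deposited length equalled the number of bases in the union of the gene's exons in 16591 matched genes. Symbols were the same in 16411. Position, length and symbol were not compared for genes that matched only without the version. Positions in the text are those of the deposited table, counted from 1. The 31 gene lists, holding 682 distinct genes, were fixed before the data were examined, and their symbols were matched to those of the table as written. Genes without a row were not analysed here.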

Results

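The samples were mouse papilloma organoids, which are epithelial cultures grown in 3 dimensions, profiled by RNA sequencing. The labels describe 12 samples in 4 groups of 3. Organoids labelled Smad4-positive came from line 1061 and organoids labelled Smad4-negative from line 1059, so genotype and organoid line coincided in this design. Each line received either vehicle (DMSO) or SB431542 at 10 µM. Sample titles open with numbers that recur across the groups, and the meaning of these numbers was not resolved here. In the Smad4-positive vehicle group, unlike the others, the same number recurs within the group. A title there carries an additional number that no other title has, and it was taken as written. SB431542 is an inhibitor of the type I receptors for TGF-beta, activin and nodal, encoded by Tgfbr1, Acvr1b and Acvr1c. SMAD4 is a shared partner in signalling from TGF-beta and BMP receptors to genes.

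The design implies a comparison of SB431542 with vehicle in each line, a comparison of the lines under each treatment, and a test of whether the treatment effect differed between the lines. None of these comparisons was made. The count table held 12 columns of values, and the name of each matched the labels of 0 samples. The column names ended in running numbers, and no key linking these numbers to the samples was found in the labels or the series text. Without such a key, a group could have come only from the number, the position or the values of a column. Use of the number or position would have been a guess about order. Use of the values would have assumed differences between the groups before any was tested. No fold change or test is therefore reported for any gene, and nothing here bears on how SMAD4 or SB431542 affected these organoids. Expression levels and depth over all columns needed no assignment to groups. They were not computed either, because no value column was used.

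The genes listed could be described, since their annotation belongs to no sample. The table held 17050 genes, and 17050 of them carried the protein-coding biotype. Smad4 (ENSMUSG00000024515.13), the gene named in the genotype labels, had a row. It lies on chromosome 18 from 73639009 to 73703780 of GRCm38, on the minus strand, with 3712 exonic bases. The receptor genes targeted by SB431542 also had rows. Tgfbr1 lies on chromosome 4 from 47353222 to 47414931, Acvr1b on chromosome 15 from 101174067 to 101213684, and Acvr1c on chromosome 2 from 58267453 to 58357895.

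Of 22028 protein-coding genes in GENCODE M21, 17008 had a row when identifiers were compared without their version, and 16578 when the version also had to match. The 31 gene lists covered pathways and cell states relevant to this tissue and treatment, other cell types, library quality and Y-linked genes, and 636 of their 682 distinct genes had a row. Every member had a row in 16 of the lists. All 30 of the 30 listed TGF-beta target genes had a row, among them Smad7 on chromosome 18 from 75367529 to 75395935. Of 25 listed WNT/beta-catenin target genes, 24 had a row, among them Axin2, a feedback inhibitor of the pathway, on chromosome 11 from 108920349 to 108950783. Lgr5, a receptor for R-spondins, lies on chromosome 10 from 115450311 to 115587780. The basal keratinocyte list had rows for 20 of 20 genes, including the keratins Krt5 and Krt14, and the differentiating keratinocyte list for 34 of 34, including Krt13. Among markers of other cell types, rows were found for 15 of 16 fibroblast genes, 11 of 12 endothelial genes, 15 of 16 simple or glandular epithelium genes, 15 of 20 immune genes, 11 of 14 muscle genes and 9 of 12 melanocyte, Schwann or Merkel cell genes. Of 4 Y-linked genes, 2 had a row. The replication histone list had rows for 0 of 21 genes by the symbols as written, and for 19 of 21 when the GENCODE M21 symbols were also matched. The presence of a row says that a gene was listed. Whether genes had been selected for listing by their counts was not examined, so a row is not read here as expression.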

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

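No result on expression was computed, so no alternative setting for such a result was run. No paired analysis was possible because the names of the value columns matched no sample or replicate label. The fixed design also held no block for the numbers that open the sample titles. The alternatives given here were chosen after seeing the data and concern annotation only. Matching identifiers without their version raised the number of genes found in GENCODE M21 from 16591 to 17034 of 17050. The number of GENCODE M21 protein-coding genes with a row was 17008 without the version and 16578 with it. Matching listed genes by their GENCODE M21 symbol as well raised the number with a row from 636 to 655 of 682, through 19 histone genes that the table gives under other symbols.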
